A study of Mus musculus with 14 samples.

How the data were processed

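The series holds 14 samples of mouse bone marrow cells. The 8 RNA-seq libraries were used: control and KO LSK, control and KO MyePro (1 library each), and 2 control and 2 KO LT-HSC libraries. The 6 ChIP-seq samples (input, H3K4me3 and H3K27me3 in lineage-negative cells of each genotype) were not analysed here. Groups were taken from the genotype and cell type in the labels. Per the labels' protocols, RNA was selected for polyA in 2 rounds, LT-HSC RNA was amplified with the Ovation RNA-seq System V2 before library preparation, and the other RNA was not amplified. Each library was pooled from several mice, so the replicates are pools.

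The deposited values are raw counts per gene, 1 file per library. Per the submitters' processing notes, the tools used for the series included CASAVA 1.8.4, TopHat2, Picard 1.126, HTSeq 0.6.0, DESeq 3.0 and bedtools 2.17.0 with build mm10, and for ChIP-seq-type data Bowtie2, MACS 1.4.2, ChIPseeker 1.8.0 and HOMER 4.8. The role and order of each tool, the annotation and the strand setting are not given in the sources used here, so overlapping and antisense genes and near-identical copies such as globin, granzyme, Hist1 and immunoglobulin genes could share reads. The deposited LSK and MyePro counts are listed by gene symbol (38926 entries) and the LT-HSC counts by Ensembl ID (39179 IDs, with 92 ERCC spike-in entries), and 37607 of the IDs (96.0%) were matched to a symbol. Positions are from the RefSeq annotation of GRCm38.p6. The 2 sets of libraries were normalized and analysed apart.

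Entries that name no gene were left out of library sizes and tests. Reads without a feature made up 21.0%, 23.5%, 16.7% and 26.0% of the file totals in control LT-HSC 1 and 2 and KO LT-HSC 1 and 2, and 6.25%, 3.83%, 2.40% and 5.86% in control LSK, KO LSK, control MyePro and KO MyePro. Reads aligned to more than 1 place made up 28.5%, 25.9%, 23.9% and 25.4%, and 37.9%, 29.9%, 33.4% and 35.0%, in the same order. An entry named DPY30-SPKIG in the LSK and MyePro files, which the labels do not explain, was kept out as well. ERCC reads made up 0.934%, 0.882%, 1.18% and 0.596% of the LT-HSC gene and ERCC counts. Mitochondrial ribosomal RNA took 45.1%, 49.6%, 62.4% and 49.3% of LT-HSC gene counts. Library depth ran from 6130320 gene counts (KO LSK) to 85499797 (KO LT-HSC 1).

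LT-HSC libraries were compared with edgeR 4.0.16 (R 4.3.3): TMM normalization, genes with at least 1 CPM in at least 2 of 4 libraries, quasi-likelihood fit and test, two-sided, with a Benjamini-Hochberg adjusted p under 0.05. This fit had no block. Control and KO libraries of the same number share a transplant per the labels, so the numbers pair the samples, and the fit with transplant as a block is given beside each result it changes. As a check, the deviations of same-numbered libraries from their group means correlated at 0.292 across genes. Control 1 and KO 1 correlated at 0.911 and control 2 and KO 2 at 0.875 in log2 CPM, against 0.837 between controls, 0.870 between KO libraries, 0.882 for control 1 and KO 2 and 0.821 for control 2 and KO 1, so that same-numbered libraries were not always the closest. A split by transplant gave 13 genes past the threshold and 1513 at an unadjusted p under 0.05. Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01, adjusted over 33 lists), and the calls were recomputed with an estimated correlation and with fry, under both of which 0 lists passed. The means and SDs given are of TMM-normalized CPM over 2 libraries.

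For LSK and MyePro no test across libraries was made, since a fit over both populations would use them as replicates of each other. Log2 ratios of TMM-normalized CPM were computed with a prior count of 2, genes with a mean of at least 5 CPM over the libraries compared were counted at a 2-fold difference, and 95% intervals for single genes cover counting error only. A gene near 0 in a library thus enters only if it is high in another. List medians were set against 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Where a library had 0 counts, the fold was computed against a floor of 3 counts, per library in LSK and MyePro and over the group in LT-HSC.

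The comparisons, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named Dpy30, then in LT-HSC the up to 10 genes per direction with the largest fold change past the threshold (both KO libraries on the same side of both controls, mean of at least 5 CPM, no Gm, Rik, pseudogene or ribosomal protein symbols), filled up to 5 with the smallest p-values. In LSK and MyePro it named the 10 highest and 10 lowest log2 ratios of each comparison among genes with a mean of at least 10 CPM. For each list it named up to 4 members past the threshold or past 2-fold, or else the 2 most highly expressed, and any member of the H3K4 methyltransferase complexes and HSC regulators. Named after their values were seen were Ermap, Klf4 and Nr4a1 in LT-HSC, Klf1 and Pf4 in the plot of KO effects, and the globin genes as a set. Some genes that the rule named are not reported here.

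The steps were tested on simulated counts with the means and library sizes of the real libraries. For 12288 genes the dispersion was that estimated from the LT-HSC libraries (biological coefficient of variation 0.497). At a log2 fold change of 1 the edgeR test recovered 2 of 48 changed genes, and at 2 it recovered 19 of 45. It recovered 36 of 49 changed by 3 and 39 of 46 changed by 4, with 6 false calls. Small changes in LT-HSC were thus mostly not detectable by the fit without a block. No transplant effect was simulated, so the power of the fit with the block was not examined. Camera, run on 12844 simulated genes, called a list shifted by a log2 of 1 downward in 10 of 10 runs. It gave an unadjusted p under 0.05 in 8 of 310 tests of unshifted lists. Genes were simulated independently of each other, so this rate does not hold for real lists whose members correlate. For LSK, with counting noise only and 10297 genes, 191 of 192 changed genes were recovered past 2-fold and 0 unchanged genes passed. All planted changes were larger than 2-fold, so this run does not show the sensitivity near that threshold. Variation between animals or libraries was not simulated, so it also does not show how many unchanged genes pass 2-fold in real libraries.

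Alternatives were the transplant block, RLE size factors, upper quartile normalization, library totals, DESeq2 1.42.0 with and without the block, limma-voom, other expression filters, an adjusted p threshold of 0.1, each LT-HSC library left out in turn, and for LSK and MyePro library totals, RLE size factors, prior counts of 0.5 and 5 and mean CPM minimums of 1 and 20. Added after the data were seen were ERCC size factors, a fit without Y-linked genes and Xist, counts thinned to the smallest library, and the 100 LT-HSC genes with the smallest p in each direction.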

Results

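RNA was sequenced from 3 populations of mouse bone marrow cells, each in a control and a Dpy30 knockout (KO) background. DPY30 is a core subunit shared by the SET1 and MLL complexes, which methylate lysine 4 of histone H3. Control cells carried the Mx1-Cre transgene with 1 floxed and 1 wild-type Dpy30 allele, and KO cells carried Mx1-Cre with 1 floxed and 1 null allele. Donor marrow was transplanted with competitor marrow, the recipients received 4 injections of pIpC (7.5 µg/g), which switches on Mx1-Cre, from 7 weeks after transplantation, and cells were sorted 2 weeks after the last injection. Long-term hematopoietic stem cells (LT-HSC) came as 2 control and 2 KO libraries from transplants 1 and 2, each pooled from 7 to 9 mice and amplified before library preparation. LSK cells, the fraction that holds stem cells and multipotent progenitors, and the more differentiated MyePro cells came as 1 library per genotype, each pooled from 2 to 3 mice and not amplified. The labels do not give the MyePro gate.

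The LT-HSC libraries held 38473360 and 38060087 gene counts in control and 85499797 and 54123123 in the libraries labelled KO. Control and KO LSK held 14974432 and 6130320, and control and KO MyePro held 20820762 and 11531994. With 1 library per group, no difference involving LSK or MyePro has a replicate check, so those comparisons are given as values without p-values. Their 95% intervals cover counting error only.

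Dpy30 (ENSMUSG00000024067; GRCm38.p6, chromosome 17, 74299474 to 74323944) was lower in KO LSK and KO MyePro than in their controls, but not in both libraries labelled KO from LT-HSC. In LSK it stood at 78.0 CPM (TMM-normalized counts scaled to 1e6 per library) in control and 42.4 CPM in KO, 54.4% of the control level (log2 ratio -0.88, interval -1.07 to -0.69). In MyePro it stood at 113 and 51.9 CPM, 45.8% of the control level (log2 ratio -1.13). In LT-HSC the controls held 12.9 and 8.43 CPM and the libraries labelled KO held 14.1 CPM (transplant 1) and 4.67 CPM (transplant 2). The LT-HSC log2 fold change was -0.19 ± 0.605 (SE, n = 2 per group; adjusted p = 0.999, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The value was 0.16 without control LT-HSC 1, 0.40 without KO LT-HSC 2 and -1.19 without KO LT-HSC 1. The counts cover all exons of Dpy30, and the labels do not say which part is deleted, so the level of the gene checks the genotype only in part. Every LT-HSC direction below is drawn from libraries labelled KO, of which KO LT-HSC 1 was not lower in Dpy30.

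**Figure D1:**
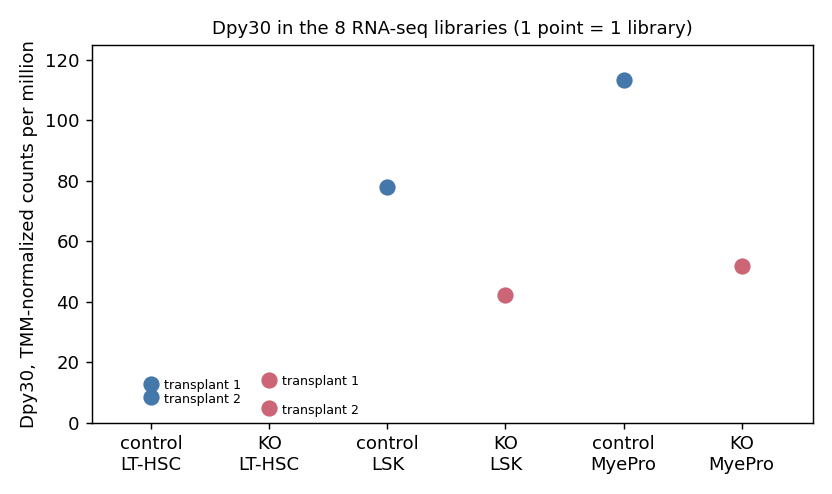
TMM-normalized Dpy30 CPM (vertical axis, linear from 0) in each of the 8 RNA-seq libraries, 1 point per library, with LT-HSC normalized separately from LSK and MyePro and amplified, so levels are comparable only within LT-HSC or within LSK and MyePro. KO lay below control in LSK (42.4 against 78.0) and MyePro (51.9 against 113), while the libraries labelled KO from LT-HSC lay at 14.1 and 4.67 around controls at 12.9 and 8.43.

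The LT-HSC comparison addressed how gene expression differs between control and Dpy30 KO stem cells. The genes with the clearest differences were sex-linked. Kdm5d, a Y-linked histone H3K4 demethylase (chromosome Y, 897566 to 943813), stood at 29.8 and 19.2 CPM in the controls and at 0 counts in both libraries labelled KO, at least 968-fold lower against a floor of 3 counts over the group (adjusted p = 0.0433, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Eif2s3y, a Y-linked translation factor gene (chromosome Y, 1010562 to 1049134), fell from 17.5 ± 2.98 CPM to 0.0798 ± 0.0298 CPM (SD, n = 2), a log2 fold change of -7.76 ± 0.656 (SE; adjusted p = 0.0433, same edgeR test). Xist (chromosome X, 103460373 to 103483233), the RNA that coats the inactive X chromosome, stood at 194 ± 63.3 CPM in control and 1834 ± 468 CPM in the libraries labelled KO (log2 fold change 3.24), and Y-linked Ddx3y stood at 11.6 ± 4.07 and 0.0147 ± 0.0208 CPM (log2 fold change -9.26). Neither passed the edgeR quasi-likelihood threshold (adjusted p = 0.210 and 0.190). Both passed it with transplant number as a block (adjusted p = 0.00336 and 0.0203), which gave 4 genes past the threshold in place of 2.

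Of 12844 genes tested in LT-HSC, 0 rose and 2 fell at an adjusted p under 0.05 with the edgeR quasi-likelihood test. At an unadjusted p under 0.05, 130 were higher and 164 lower. DESeq2 called 5 higher and 9 lower, 9 of the 14 not sex-linked, and limma-voom called 1 gene, Xist. The remaining genes with the smallest p-values were Cox4i2 (0.0886 ± 0.0273 against 4.88 ± 1.29 CPM), Igkv1-110 (0.0231 ± 0.0327 against 3.88 ± 1.78), Snora7a and Skida1 on the higher side and Uty (17.4 ± 0.461 against 1.59 ± 0.332 CPM) and the immunoglobulin gene Ighg2b (11.0 ± 3.26 against 0.545 ± 0.143 CPM) on the lower side, none past the threshold (edgeR adjusted p from 0.438 to 0.999). The libraries labelled KO both lay outside both controls on the same side for 27.7% of genes. The share would be 33.3% if the 4 libraries were exchangeable, which libraries paired by transplant are not. Without either control library the count of genes past the threshold was 0, and Kdm5d and Eif2s3y then failed the expression filter, and it was 5 without KO LT-HSC 2.

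Of the gene lists, 6 were called in LT-HSC by camera with the preset correlation, and 0 with an estimated correlation or with fry. Erythroid genes were lower: the median log2 fold change of 26 measured members was -0.78, 23 were negative, and for 13 both libraries labelled KO lay below both controls (camera adjusted p = 1.82e-06, and adjusted p = 0.629 with an estimated correlation). The medians were -0.69 in transplant 1 and -0.92 in transplant 2. None of the members passed the edgeR threshold over all genes or adjusted over the list alone, and 4 were lower at an unadjusted p under 0.05. The most highly expressed members, Car2 (203 ± 111 against 153 ± 9.99 CPM) and Zfpm1 (44.1 ± 19.7 against 36.2 ± 7.79 CPM), had log2 fold changes of -0.41 and -0.28. Ermap, an erythroid membrane protein gene chosen after its values were seen, stood at 21.5 ± 2.45 against 9.76 ± 0.335 CPM. Heme and iron genes were also lower (22 members, median -0.27, camera adjusted p = 0.0183, and 0.893 with an estimated correlation). The call of the LT-HSC list Heme and iron was lost without control LT-HSC 2 (camera adjusted p = 0.0909), without KO LT-HSC 2 (0.120) and with library totals (0.104), as well as with ERCC size factors (0.102).

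Immediate early and dissociation stress genes were lower in the libraries labelled KO, with 17 of 20 members negative and a median of -0.82 (camera adjusted p = 0.00127, and 0.912 with an estimated correlation). Adjusted over the list alone, 1 member rose and 1 fell by the edgeR quasi-likelihood test: Klf4 (chosen after its values were seen, like Nr4a1) stood at 0.905 ± 0.0278 against 6.14 ± 1.70 CPM and Nr4a1 at 12.0 ± 7.63 against 1.24 ± 0.131 CPM, while over all genes tested 0 passed. The call of the LT-HSC list Immediate early and dissociation stress was lost without control LT-HSC 2 (camera adjusted p = 0.160) and without KO LT-HSC 2 (0.0569). Macrophage and dendritic cell genes were higher (14 members, median 0.67, camera adjusted p = 0.0491, and 0.912 with an estimated correlation). The call of the LT-HSC list Macrophage and dendritic cell genes ended under the transplant block (camera adjusted p = 0.0740), without control LT-HSC 1 (0.815), without KO LT-HSC 2 (0.238), with library totals (0.187), with ERCC size factors (0.162) and without Y-linked genes and Xist (0.0561). In the LT-HSC list Mitochondrially encoded genes all 21 members had positive values (median 0.84, camera adjusted p = 2.97e-05, and 0.912 with an estimated correlation). Without KO LT-HSC 1, in which mitochondrial ribosomal RNA took 62.4% of gene counts against 45.1% and 49.6% in the controls and 49.3% in KO LT-HSC 2, the median was -0.03 (camera adjusted p = 0.936), and without control LT-HSC 1 the camera adjusted p was 0.120. The 5 sex-linked genes made up the last called list (median -7.76, camera adjusted p = 8.4e-09, and 0.629 with an estimated correlation). Adjusted over the list alone, 1 of them was higher and 4 lower.

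The other 27 of the 33 lists were not called in LT-HSC. Members of the H3K4 methyltransferase complexes had a median of -0.20, with 16 of 18 negative (camera adjusted p = 0.112). Among them Kmt2a stood at 424 ± 84.3 against 369 ± 11.0 CPM and Kmt2c at 242 ± 6.87 against 211 ± 3.05 CPM. HSC regulators had a median of -0.04 (adjusted p = 0.445), HSC surface and signature genes 0.18 (0.0973), the Hoxa and Hoxb cluster 0.31 (0.395), megakaryocyte genes -0.02 (0.808), lymphoid priming genes -0.32 (0.395), mitosis genes -0.10 (0.450) and ribosome biogenesis genes -0.07 (0.504), all by camera. Hoxa9, low in KO LSK below, stood at 9.55 ± 6.58 against 12.2 ± 5.92 CPM. The median and the camera direction differed in sign for the T and NK cell, oxidative phosphorylation and mature neutrophil lists, and the median and the mean for the antioxidant, oxidative phosphorylation and megakaryocyte lists, none of them called.

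The comparison of KO with control LSK addressed the multipotent progenitor fraction. Erythroid genes were lower in KO LSK, some markers of neutrophils, macrophages and cytotoxic cells were higher, and several transcription factors of stem cells were lower. Of 22 erythroid genes with a mean of at least 5 CPM, 12 were at least 2-fold lower and 2 at least 2-fold higher, with a median log2 ratio of -1.41, at percentile 0 of 10000 random lists of the same size matched on expression. The erythroid membrane gene Ermap stood at 98.9 CPM in control and 1.06 CPM in KO (log2 ratio -6.35), the Rh blood group genes Rhd and Rhag had log2 ratios of -5.22 and -4.84, Ank1 had -4.87, and carbonic anhydrase Car1 stood at 495 and 21.0 CPM (-4.55). Pklr, the red cell pyruvate kinase, stood at 33.7 CPM in control and 0 in KO, at least 74.2-fold lower against a floor of 3 counts per library. Globin genes went the other way and are described with the MyePro values.

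Among HSC regulators, 7 of 37 were at least 2-fold lower in KO LSK and 1, Hoxb4, was higher (median -0.35, percentile 0.05). Hoxa9 (chromosome 6, 52223097 to 52227370) stood at 41.4 against 3.63 CPM (log2 ratio -3.46), Prdm16 at 18.9 against 2.27 (-2.97), Hlf at 194 against 45.2 (-2.10) and Mecom at 41.4 against 10.4 (-1.97). Other Hoxa cluster genes were low as well, Hoxa10 at 16.0 against 0.605 CPM (4 counts in KO) and Hoxa7 at 17.9 against 6.81 CPM, and the 4 measured genes of the Hoxa and Hoxb cluster had a median of -2.42 (3 lower, 1 higher). HSC surface and signature genes were split, with 2 higher and 7 lower of 27. Krt18 (-3.83) and Vwf (-3.20) were lower, while Mmrn1 stood at 28.4 against 251 CPM (3.14) and Fhl1 at 9.98 against 58.1 CPM (2.52). The median of that list was -0.01 and turned positive with library totals (0.12), RLE size factors (0.02) and thinned counts (0.01). Of 15 lymphoid priming genes 6 were lower and 0 higher (median -0.62, percentile 0), including Dntt, which encodes terminal transferase (57.0 against 5.75 CPM), Cd27 (159 against 21.3) and the receptor gene Flt3 (log2 ratio -1.77).

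The highest values in KO LSK belonged to genes that were nearly silent in control. The neutrophil alarmin gene S100a8 stood at 0 in control and 60.4 CPM in KO, at least 296-fold higher, and the granzyme gene Gzmc at 0 and 20.7 CPM, at least 101.7-fold higher. Frzb (chromosome 2, 80411970 to 80447396), which encodes a secreted Wnt antagonist, had 3 counts in control and 301 in KO (log2 ratio 7.00, interval 6.24 to 10.09). Gfra2 (chromosome 14, 70890107 to 70979840), a receptor of the GDNF family, had 1 count in control and 329 in KO (7.83, interval 7.03 to 14.83). Scin, an actin-severing protein gene with more counts in both libraries, stood at 18.5 and 534 CPM (4.84), Gzmb at 4.62 and 105 CPM (4.46) and Klrb1c at 0.883 and 27.8 CPM (4.76). Mrgpra2b, Zfp711 and Mgam completed the 10 highest. Besides erythroid genes, the 10 lowest included Plbd1 (43.7 CPM against 0, at least 96.4-fold lower), the amino acid transporter gene Slc38a5 (24.1 CPM against 0, at least 53.1-fold lower), Hnf4a, Smim5, Sphk1 and Ptgr1. As lists, mature neutrophil genes (4 of 5 higher, median 3.36, its middle member Lcn2), T and NK cell genes (4 of 6 higher, median 1.21), macrophage and dendritic cell genes (8 of 13 higher, 1 lower, median 1.10) and stromal and endothelial genes (5 of 9 higher, 1 lower, median 1.38) all lay at percentile 99.99 or above. Only 5 of 15 neutrophil and 6 of 22 T and NK cell genes reached the expression minimum. S100a8 and S100a9, at 0 CPM in control, reached it through the KO library alone, and Padi4 was lower (69.3 against 16.2 CPM). The T and NK cell genes Klrb1c (0.883 CPM in control), Gzmb (4.62) and Tcf7 (3.06) also reached it through the KO library. So did the stromal and endothelial genes Kdr (1.56 CPM in control) and Col1a1 (3.19), which favours higher values in these lists. Gzmb is also in the mast cell list and Nkg7 in the myeloid progenitor list. Myeloid progenitor genes were higher for 7 of 24 and lower for 2, with Ms4a3 at 95.6 against 468 CPM and Fcgr3 at a log2 ratio of 2.17. Mast cell, basophil and eosinophil genes divided, with Fcer1a (2.79) and Gzmb higher and Prg2 (-4.57) and Prss34 (-3.92) lower.

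Mitosis and ribosome biogenesis genes were modestly lower in KO LSK. All but 1 of 35 mitosis genes had negative ratios (median -0.64, percentile 0), and 5 were at least 2-fold lower, among them Plk1 (-1.70) and Mki67, whose level was 284 CPM in control and 89.4 CPM in KO (-1.66). DNA replication genes had a median of -0.29 with 0 of 38 past 2-fold, and the cyclin, CDK and CDK inhibitor list had a median of 0.14 (1 higher, 2 lower of 17). All 40 ribosome biogenesis genes had negative ratios (median -0.52, percentile 0) without any passing 2-fold, with Ncl at -0.77 and Npm1 at -0.65. The p53 target genes had a median of 0.32 (5 of 27 higher, percentile 99.7), with Cdkn1a, the p21 inhibitor gene, at 14.5 against 34.5 CPM. H3K4 methyltransferase complex members had a median of -0.29 (percentile 1.90), and besides Dpy30 the lowest were Hcfc1 (-0.65), Ncoa6 (-0.63) and Kmt2c (-0.61). In LSK KO versus control, genes past a fold of 2 numbered 514 higher and 555 lower of 10311. With library totals, which moved the median log2 ratio of all genes from -0.04 to 0.09, the counts were 648 and 457.

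The same comparison in MyePro cells gave larger numbers, 1162 genes at least 2-fold higher and 810 lower in KO of 10245. Megakaryocyte genes were mostly higher: 20 of 22 passed 2-fold, 0 were lower, and the median was 3.18 (percentile 100). The other 2 lay within 2-fold, among them Vwf at 20.8 against 27.8 CPM. The platelet chemokine gene Ppbp stood at 0.701 against 78.5 CPM (log2 ratio 6.53), Mmrn1 at 4.51 against 227 (5.61) and Clec1b at 1.00 against 49.7 (5.43). KO MyePro also had more reads without a feature than control MyePro (5.86% against 2.40%) and more counts on ribosomal RNA entries (5.14% against 1.02%), while in LSK the control library was the higher (6.25% against 3.83%, and 5.45% against 1.71%). HSC surface and signature genes were higher for 14 of 23 and lower for 2 (median 1.30, percentile 100), with Fhl1 at 1.65 against 72.2 CPM, Trpc6 at 1.60 against 48.1 and the junction protein gene Esam at a log2 ratio of 4.74. HSC regulators, lower as a list in LSK, had 12 higher and 3 lower of 33 in MyePro (median 0.32, percentile 99.95), with the angiopoietin receptor gene Tek (3.49) and Mycn (2.53) among the highest. Hoxa9 remained low at 24.3 against 1.15 CPM (-4.24).

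Erythroid genes were lower in KO MyePro as well, with 16 of 23 lower and 3 higher (median -2.06, percentile 0). Ermap stood at 443 against 28.5 CPM (-3.95), Ank1, the red cell ankyrin gene, at 111 against 6.79 CPM (-4.00), Pklr at 161 against 8.29 CPM (-4.25) and Rhd at 103 against 7.85 CPM (-3.69). Tmem56, Atp7b, Add2, Smim1 and Sphk1 were the other lowest genes, each with a log2 ratio between -4.14 and -3.76. Heme and iron genes followed, with 8 of 21 lower and 1 higher (median -0.76, percentile 0.01), led by Cpox, an enzyme of heme synthesis (307 against 48.4 CPM), and the transferrin receptor gene Tfrc (404 against 108 CPM), while Hmox1 was higher (13.9 against 154 CPM). The 4 globin genes, singled out after their values were seen and taken without the expression minimum, which Hba-a1 and Hba-a2 missed in LSK, were higher in KO, with a median of 2.04 in LSK and 3.18 in MyePro, and Hbb-bs stood at 2.36 against 36.7 CPM in MyePro. The 20 other erythroid genes with a mean of at least 5 CPM in MyePro had medians of -2.14 in LSK and -2.37 in MyePro.

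Markers of several other cell types were higher in KO MyePro than in control MyePro. This held for mature neutrophil genes (7 of 8 higher, 1 lower, median 4.42), macrophage and dendritic cell genes (10 of 14 higher, 1 lower, median 2.85), T and NK cell genes (5 of 5, median 2.23) and stromal and endothelial genes (9 of 9, median 2.53). Only 5 of 22 T and NK cell and 9 of 21 stromal and endothelial genes reached the expression minimum. Klrb1c (0.150 CPM in control), Kdr (1.05), Fabp4 (0.601) and Col1a1 (1.55) reached it through the KO library, so these counts favour higher values. Lymphoid priming genes did not follow (4 higher and 6 lower of 13, median -0.55, percentile 1.755). Mast cell, basophil and eosinophil genes divided (5 higher and 3 lower of 10, median 1.14). Among the lists that rose, S100a9 stood at 0.701 against 64.4 CPM, C1qa at 3.41 against 41.7 CPM and Kdr, an endothelial receptor gene, at 1.05 against 26.8 CPM. Of 24 myeloid progenitor genes, 8 were higher and 4 lower (median 0.47), with Lyz2 at 175 against 1797 CPM and Irf8 at 218 against 48.5 CPM. Gfra2 was the highest single gene (112 CPM in KO, log2 ratio 8.31), followed by Crisp3 (0 against 26.6 CPM, at least 177-fold higher), Ppbp, Heph (0.501 against 58.8 CPM), S100a9, Aplnr, Cd38, Mmrn1, Mrgpra2a and Clec1b. Ribosome biogenesis genes were lower, 26 of 40 by at least 2-fold (median -1.12, percentile 0), with Npm1 at 2363 against 836 CPM. Mitosis (median -0.63, 7 of 35 lower), DNA replication (-0.61, 5 of 37 lower) and DNA repair genes (-0.67, 9 of 39 lower) were lower, all at percentile 0. Immediate early and dissociation stress genes were higher (10 of 17, 2 lower, median 1.40), as were 9 of 27 p53 targets, with Cdkn1a at 8.47 against 60.4 CPM, while the p53 list median of 0.22 lay within the range of random lists (percentile 90.4). Medians and means differed in sign for the cyclin and glycolysis lists in LSK and for the unfolded protein, antioxidant and oxidative phosphorylation lists in MyePro.

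**Figure D2:**
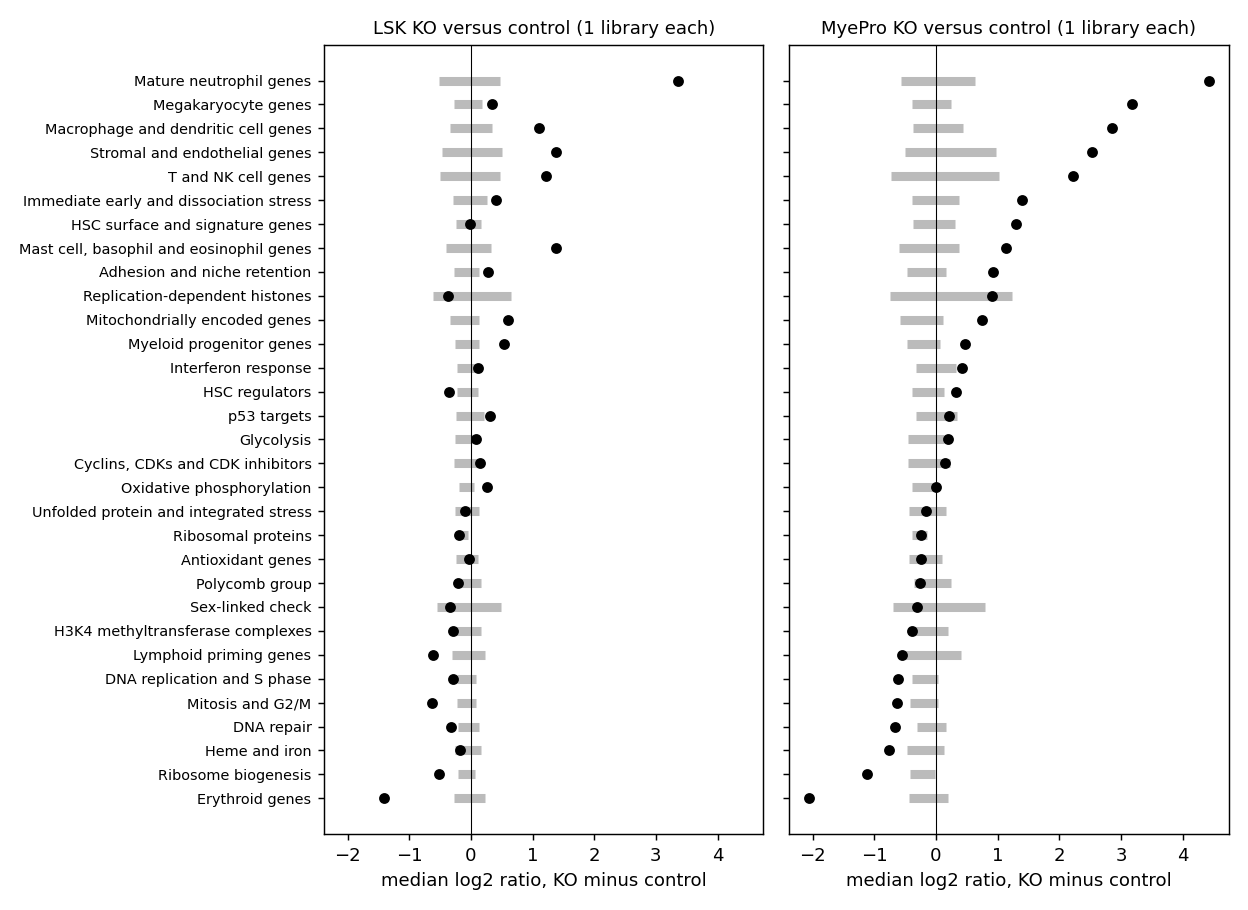
Median log2 ratio of KO over control (horizontal axis) of each gene list with at least 3 measured members in both populations in LSK (left) and MyePro (right), with 1 library per genotype; black points are list medians and grey bars span the middle 95% of medians of 10000 random lists of the same size matched on mean expression. Among the lists drawn, mature neutrophil genes lay highest (3.36 and 4.42) and erythroid genes lowest (-1.41 and -2.06), and megakaryocyte genes stood at 0.35 in LSK and 3.18 in MyePro.

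The KO effects in LSK and MyePro, which share no library, ran in parallel across genes. The labels do not say that these populations came from separate animals, so the parallel is not an independent replication. Over 10318 genes with a mean of at least 5 CPM over the 4 libraries, the log2 ratios had a Pearson correlation of 0.746 and a Spearman correlation of 0.722 (genes are not independent replicates). Of these genes, 469 were at least 2-fold higher in both and 343 lower in both, where independent lists would give 62.4 and 43.2, and 22 passed 2-fold in opposite directions. Across 9876 genes, the LT-HSC fold changes had correlations of -0.00385 with LSK and 0.00823 with MyePro.

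**Figure D3:**
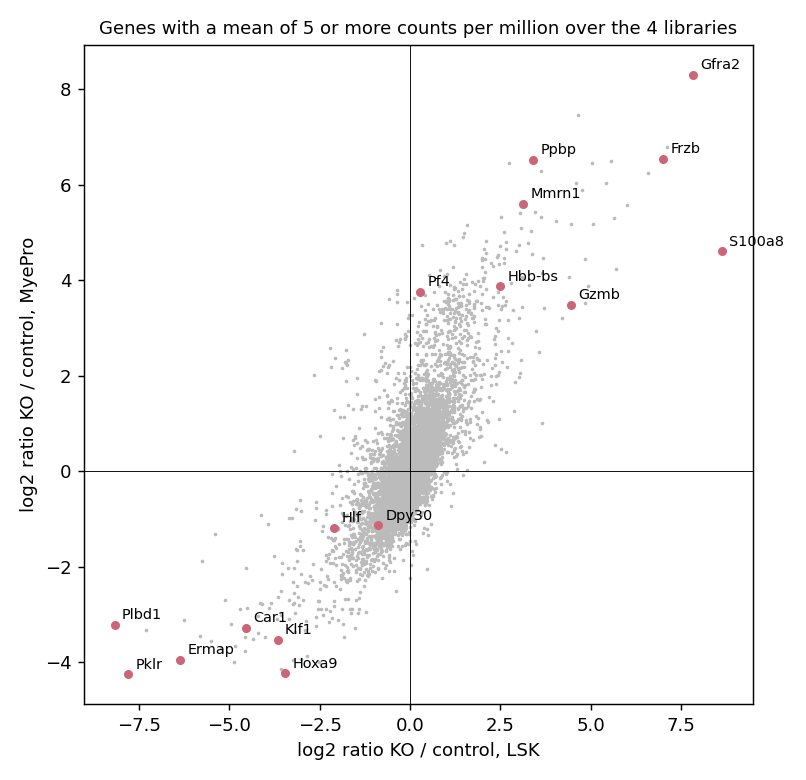
Log2 ratio of KO over control in LSK (horizontal axis) against that in MyePro (vertical axis), 1 grey point per gene with a mean of at least 5 CPM over the 4 libraries and named genes in red; genes without counts in 1 library are drawn at a value that depends on the prior count of 2. The points run along a diagonal (Pearson correlation 0.746), with Pklr, Ermap, Klf1 and Hoxa9 low in both and Pf4 higher in MyePro alone among the named genes.

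The LSK and MyePro libraries were made to follow differentiation between these populations with and without Dpy30. In control, stem cell, megakaryocyte and lymphoid genes were lower in MyePro and erythroid and myeloid progenitor genes were higher. HSC surface and signature genes were lower for 21 of 26 (median -2.08, percentile 0), with Esam at 20.5 CPM in LSK and 0.601 CPM in MyePro (-4.78) and Procr at 13.9 and 0.952 CPM (-3.67). Megakaryocyte genes were lower for 17 of 19 (median -1.67), HSC regulators for 12 of 36 (median -0.72), led by Mecom (-4.45) and Hlf (-3.82), and lymphoid priming genes for 7 of 14, led by Dntt (-3.62). Erythroid genes were higher for 17 of 20 (median 1.95), with Rhd (2.61) and Rhag (2.59) among the highest. Myeloid progenitor genes were higher for 14 of 25 (median 1.33). Among them Ly6c2 had the highest ratio, 37.5 against 397 CPM (3.40), and neutrophil elastase, Elane, stood at 224 and 1582 CPM (2.82). Sgms2, Abcg4, Tmem56, Prg2, Aldh1a7, Smim1, Nxpe2 and Mtus1 were the other highest genes. The immunoglobulin genes Igkc (50.4 CPM against 0, at least 335-fold lower) and Igha (26.9 CPM against 0, at least 179-fold lower) headed the lowest, with Pglyrp2, Vldlr, F11r and Col4a2. Of 10059 genes, 303 were at least 2-fold higher and 725 lower in control MyePro.

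In KO, the change from LSK to MyePro was smaller and of another make-up. In LSK to MyePro in KO, genes past a fold of 2 numbered 328 higher and 159 lower of 10366, and with library totals, which moved the median of all genes from 0.00 to -0.13, the counts were 246 and 234. The standard deviation of the change over genes was 0.497 in KO and 0.713 in control, and the changes had a Pearson correlation of 0.412 and a Spearman correlation of 0.348 across 10318 genes. Between libraries, log2 CPM values correlated at 0.956 for KO LSK and KO MyePro and at 0.931 for control LSK and control MyePro. Erythroid genes were higher in KO MyePro than in KO LSK for 11 of 19 (median 1.52), with Ermap at 4.56, and myeloid progenitor genes for 8 of 24 (median 0.85). Megakaryocyte genes, lower in control MyePro, were higher in KO MyePro for 7 of 22 and lower for 0 (median 0.89), with Gp1bb at 2.33 and the platelet chemokine gene Pf4 at 1.81. HSC surface and signature genes had a median of -0.01, with Procr (-2.73) and Ly6a (-2.41) still lower and Vwf higher (1.46).

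Taken as the difference of the KO change from the control change, 822 genes were at least 2-fold higher and 143 lower of 10318. All 21 megakaryocyte genes were higher (median 2.52, percentile 100), with Gp1bb at 4.16, Vwf at 3.61 and Pf4 at 3.49. Stromal and endothelial genes (6 of 8 higher, 0 lower, median 2.11), macrophage and dendritic cell genes (8 of 14 higher, 1 lower, median 1.52) and immediate early and dissociation stress genes (8 of 17 higher, 0 lower, median 0.92) were higher as well. HSC surface and signature genes were higher for 16 of 25 and lower for 0 (median 1.70), and HSC regulators for 13 of 36 and lower for 1 (median 0.48), with Tek (3.01) and Meis1 (2.43) among the highest. All 40 ribosome biogenesis genes were negative (median -0.60, percentile 0), and heme and iron genes had a median of -0.42 (percentile 0.01). Erythroid genes went the other way as a list, with 6 higher and 3 lower of 22 (median 0.51, percentile 100). Esam (4.42), Col4a2 (4.30), Vldlr (4.14) and Gem (3.92) were among the highest genes, and Car2 (-2.11), Pyhin1 (-2.26) and Ighm (-1.76) among the lowest. Plbd1, Slc38a5 and S100a8 also stood among them, but each had 0 counts in 1 LSK library, so their values depend on the prior count. Lars2 (11211 CPM in control LSK, 3058 in KO LSK and 9074 in KO MyePro), mmu-mir-6236 and mmu-mir-6240 were also among the highest, and the ribosomal RNA entries Gm42418, Gm26924 and Gm26917 together took 5.45% and 1.71% of gene counts in control and KO LSK and 1.02% and 5.14% in control and KO MyePro. Mitochondrial ribosomal RNA took 0.202%, 0.132%, 0.0727% and 0.317% in the same order.

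**Figure D4:**
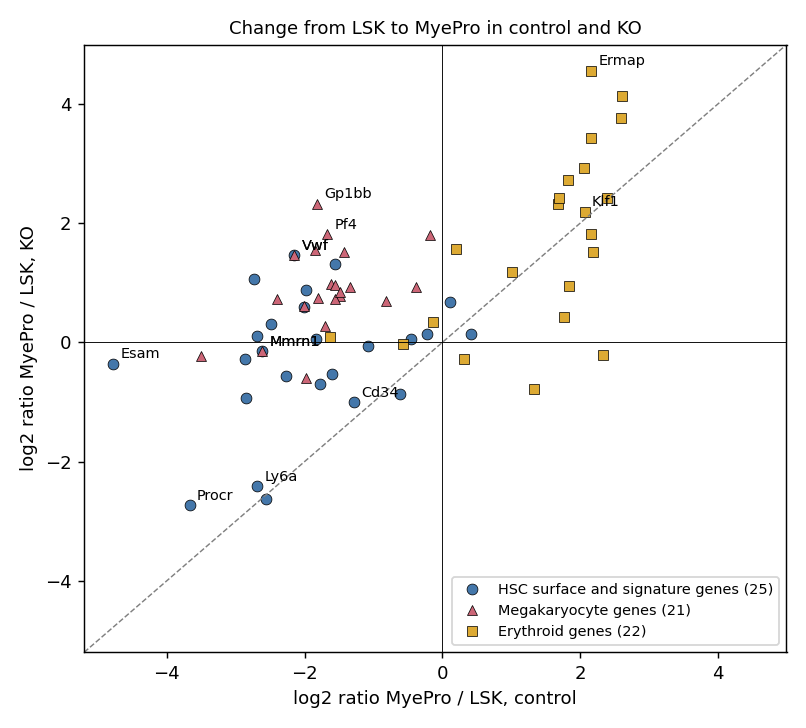
Log2 ratio of MyePro over LSK in control (horizontal axis) against that in KO (vertical axis) for members of 3 gene lists, 1 point per gene with a mean of at least 5 CPM over the 4 libraries; the dashed line marks equal changes. Megakaryocyte genes (triangles) lie left of 0 in control and mostly above 0 in KO, HSC genes (circles) are spread along 0 in KO except a few such as Procr and Ly6a near the line, and erythroid genes (squares) lie mostly at positive values in both.

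Gene sets chosen on the control change, among genes with a mean of at least 5 CPM over all 4 libraries rather than the 2 control libraries used for the counts above, showed the same contrast. Of 301 genes at least 2-fold higher in control MyePro than in control LSK, 142 were also at least 2-fold higher in KO, with medians of 1.41 in control and 0.97 in KO. Of 847 genes lower in control, 112 were also at least 2-fold lower in KO and 317 had the opposite sign, with medians of -1.51 and -0.20. Choosing the genes on the control libraries favours a larger control value. Chosen on the KO libraries instead, 323 higher genes had medians of 1.37 in KO and 0.68 in control, and 165 lower genes had medians of -1.32 in KO and -1.62 in control. Under the same minimum over 4 libraries, of the 20 HSC surface and signature genes that were at least 2-fold lower in control MyePro, 4 were also at least 2-fold lower in KO, and 8 had a ratio above 0 of any size in KO (medians -2.38 and -0.21). Of 18 such megakaryocyte genes, 0 were also at least 2-fold lower and 15 had a ratio above 0 of any size (medians -1.76 and 0.81).

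The genes past the threshold in LT-HSC, both Y-linked, did not differ much in LSK or MyePro. As the sex of the cells appears to differ between the LT-HSC groups, this says nothing about other genes. Eif2s3y had log2 ratios of 0.04 in LSK and -0.14 in MyePro and Kdm5d -0.33 and -0.18, and their medians of -0.14 and -0.16 lay at percentiles 34.9 and 39.8 of random lists. Xist stayed at or under 0.617 CPM in all 4 LSK and MyePro libraries, while Kdm5d stood between 19.8 and 29.0 CPM. The 100 genes with the smallest p in each direction in LT-HSC, sex-linked genes left out, were added as a set after the data were seen. Those higher in the libraries labelled KO had medians of 0.09 in LSK and 0.06 in MyePro, and those lower had -0.05 and -0.21, all within the range of random lists.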

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

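All tests weighed here were chosen after the result was seen, except that of the genes that escape X inactivation.

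HSC regulators stood out because their KO effect differed between populations, with a median log2 ratio of -0.35 in LSK and 0.32 in MyePro. Immediate early and dissociation stress genes did so too, with medians of -0.23 and -0.98 in transplants 1 and 2 of LT-HSC against 0.41 in LSK and 1.40 in MyePro. Neither difference was tested, since LSK and MyePro had 1 library per genotype. The entry DPY30-SPKIG, outside every comparison, stood at 396 CPM in KO LSK against 331 in control LSK and at 1011 CPM in KO MyePro against 70.6 in control MyePro. ERCC spike-in reads made up 1.18% of counts in KO LT-HSC 1, above the 0.934% and 0.882% of the controls, and 0.596% in KO LT-HSC 2, below both.

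The erythroid genes were lower in KO LSK and MyePro while the globin genes were higher. The choice among the scalings tried is argued against. Under library totals, RLE size factors and thinned counts the highest erythroid median in LSK was -1.09, while library totals moved the median of all genes by 0.13. A scaling to spike-in reads could not be tried, since the LSK and MyePro libraries held no ERCC counts. Fewer mature red cells in the KO sorts would lower globin transcripts, whose median was 2.04 in KO LSK, but these genes were picked for being higher and 2 of the 4 lay under 5 CPM, so the test decides nothing. The erythroid genes other than globins had a median of -2.37 in MyePro, as fewer erythroid-committed progenitors in the KO sorts could give, but a lower level per cell could give it too. These cannot be told apart in pooled RNA, and the biological effect of the genotype stays open.

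Y-linked genes were nearly absent and Xist was higher in the libraries labelled KO from LT-HSC. An effect of the genotype on Y-linked genes is argued against, since the lower of their medians in KO LSK and KO MyePro was -0.34. Donors of a different sex in the compared groups were tested on Kdm5c, Ddx3x and Eif2s3x, which escape X inactivation and should be higher with a second active copy. Their median log2 fold change of 0.16 lay between the bounds set beforehand, over 0.2 if donor sex was the cause and 0 or below if not, and the single values were 0.05, 0.16 and 0.56. This test could not decide, since the standard errors of the single values, 0.25 to 0.32, exceeded the bound of 0.2. Kdm5d had 1380 and 831 counts in the controls and 0 in both libraries labelled KO, so the sex of the cells appears to differ. Xist was also present in the controls, and the labels give no sex. For other genes in LT-HSC, an effect of sex cannot be told apart from that of the genotype.

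As lists, HSC surface and signature genes and megakaryocyte genes were lower in control MyePro than in control LSK (medians -2.08 and -1.67) but not in KO (medians -0.01 and 0.89), although single HSC genes such as Procr were. LSK cells in the KO MyePro sort were weighed on Ly6a, which encodes the Sca-1 antigen of the LSK gate. Its change from LSK to MyePro differed by 0.28 between KO and control, against 1.70 for the median of HSC surface and signature genes. Ly6a stood at 4.76 CPM in control MyePro and 11.5 CPM in KO MyePro. A gate on Sca-1 would itself keep Ly6a low in MyePro cells, and the labels do not give that gate. This single gene therefore cannot decide. The choice among the scalings tried is argued against. Over library totals, RLE size factors and thinned counts, the lowest difference for the median of HSC surface and signature genes was 1.61. More megakaryocyte-committed cells in the KO MyePro sort may account for the megakaryocyte list, whose median was 0.89 from KO LSK to KO MyePro, but stromal and endothelial (2.11) and macrophage and dendritic cell genes (1.52) were higher in the difference too. It cannot be told apart from higher expression per cell, or from an effect of the genotype, in pooled RNA with 1 library per group. Ribosomal RNA entries took 5.45% and 5.14% in control LSK and KO MyePro, against 1.71% and 1.02% in KO LSK and control MyePro. Reads without a feature were likewise more frequent in control LSK and KO MyePro (6.25% and 5.86%, against 3.83% and 2.40%). Control LSK and KO MyePro enter the difference with a plus sign, so the difference runs with library quality. Library quality was not tested as a cause.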

How the results depend on the processing

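Several alternatives below were added after the data were seen (ERCC size factors, the fit without Y-linked genes and Xist, thinned counts, the 100 genes with the smallest p). In LT-HSC the 2 genes past the threshold became 4 with the replicate block (1 higher, 3 lower, all sex-linked), 4 with library totals (which moved the all-gene median to -0.35), 4 without a filter, 4 with a filter of 5 CPM, 14 with DESeq2, 23 with DESeq2 and the replicate block (19 not sex-linked), 1 with limma-voom, 1 with ERCC size factors and 0 without Y-linked genes and Xist (289 at an unadjusted p under 0.05 by the edgeR test). Leaving out 1 library gave 0 to 5, with the lone library assumed to vary like the other group. Without a control, Kdm5d and Eif2s3y failed the filter, while Uty and Xist were still tested. The LT-HSC value of Dpy30 ran from -1.19 to 0.40 with 1 library left out and turned positive without control LT-HSC 1 (0.16) and without KO LT-HSC 2 (0.40). Of 6 gene lists called, 0 were called with an estimated correlation and 0 with fry. The replicate block left 5, library totals 4, ERCC size factors 4 and the fit without Y-linked genes and Xist 4, and leaving out 1 library gave 4 to 9. The block changed no other call. The cause of these changes was not tested. The replicate block with a GC and length correction was not run, as no genome was used here.

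In LSK and MyePro the expression minimum set the counts by construction, more genes being counted at a lower one. In LSK KO versus control, genes past a fold of 2 numbered 1069 in the report, 2075 at a mean of 1 CPM, 454 at 20 CPM and 1074 with thinned counts. In MyePro KO versus control, genes past a fold of 2 numbered 1972, 3275, 1068 and 1963. In LSK to MyePro in control, genes past a fold of 2 numbered 1028, 1825, 472 and 1072, and in LSK to MyePro in KO, genes past a fold of 2 numbered 487, 1335, 177 and 487. For the Difference of the LSK to MyePro change between KO and control, genes past a fold of 2 numbered 965, 2033, 370 and 1024. The LSK to MyePro in control list Macrophage and dendritic cell genes turned positive (0.0120) at 20 CPM. The medians of the LT-HSC genes turned positive, to 0.0901 in LSK and 0.0646 in MyePro, when the 100 genes with the smallest p on the higher side replaced the 2 genes, by construction another direction.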

Other observations

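Interferon response genes were not reported above. pIpC, given to both genotypes, induces interferon. In KO MyePro 8 of 29 members were at least 2-fold higher and 0 lower (median log2 ratio 0.42), with the interferon-induced protease gene Usp18 at 3.81 against 24.2 CPM and the RNA sensor gene Ddx58 at 16.6 against 76.3 CPM. In KO LSK 2 of 31 were higher (median 0.11, percentile 91.3), and both Usp18 and Ddx58 had a log2 ratio of 1.10. From LSK to MyePro in control 9 of 29 members were lower (median -0.57), with Ifi44 at 8.90 and 1.80 CPM. In LT-HSC the list was not called (median 0.16, camera adjusted p = 0.445).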
